A study of Homo sapiens with 18 samples.

How the data were processed

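The samples were HaCaT keratinocytes in 6 groups of 3 libraries: untreated, uLMW-HA, HMW-HA, UVB, uLMW-HA after UVB and HMW-HA after UVB. Per the labels' protocols, cells grew in serum-containing DMEM in 6-well plates, were washed with PBS, irradiated with broadband UVB and then given medium with or without HA. A dose of 15 mJ/cm2 is stated for the groups given HA after UVB, and the dose of the group with UVB alone is not clear from the labels. The HA concentration, the time between treatment and harvest, and whether replicates are separate cultures are not given in the sources used here. Per the labels' protocols, poly(A) RNA was selected, libraries were made with a NEBNext Ultra II RNA kit and sequenced single-end on an Illumina NovaSeq.

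The deposited files, 1 per library, hold a read count per gene in several columns (all gene reads, exon reads, intron reads and uniquely mapped reads), with TPM and RPKM values that were not used here. Per the submitters' processing notes, base calls were converted with bcl2fastq and the genome build was GRCh37, in each case without a version. The aligner, the counting tool, the annotation release and whether counting used strand are not given in the sources used here, so reads of overlapping or antisense genes could not be separated, and levels of genes with near-identical copies are uncertain. Each file lists 57773 genes, 20327 of them protein coding, and exon and intron reads add up to the count of all gene reads in every cell. Total gene reads per library had a median of 29.5M (units of 1e6 reads) and ranged from 24.8M to 43.2M, of which 90.3% to 91.3% mapped uniquely, 4.41% to 5.61% were intronic and 95.0% to 95.9% came from protein coding genes. CXCL8 is listed under IL8 and CEMIP under KIAA1199. A comparison of libraries within groups, made to look for copies of the same reads, gave chi-square values per gene of 2.14 to 20.3. Repeated sequencing of 1 library would give about 1. The values were highest within HMW-HA without UVB (8.08 to 20.3) and at most 7.66 within the other groups.

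All gene reads were tested in R 4.3.3 with edgeR 4.0.16: genes with too few reads were removed by filterByExpr (minimum count 10), 19254 genes were kept, libraries were scaled by TMM, and 1 quasi-likelihood fit of the 6 groups (robust dispersions, no block) gave every comparison, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The common biological coefficient of variation was 5.08%, with 12 residual degrees of freedom and a median of 10.2 prior degrees of freedom. Standard errors of log2 changes were taken from the quasi-likelihood F statistic, and intervals are 95%. Group levels are means of TMM-scaled counts (CPM) with the SD of 3 libraries. The 11 comparisons were UVB, uLMW-HA and HMW-HA each against untreated, each HA after UVB against UVB, the HAs against each other with and without UVB, UVB within each HA, and the interaction of UVB with each HA.

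The comparisons, their tests, the naming rule and all alternatives but 1 were fixed before the data were examined, while the tests of harvest or medium timing and of airway transcripts were chosen after results were seen. The 22 gene lists were fixed beforehand too: alarmins and antimicrobial peptides, cytokines and chemokines, NF-kappaB feedback targets, p53 targets, immediate early genes, unfolded protein and integrated stress response, NRF2 targets, interferon-stimulated genes, keratinocyte differentiation, basal keratinocyte and hemidesmosome genes, mitotic genes, DNA replication, nucleotide excision repair, hyaluronan genes, matrix proteases and inhibitors, EGF receptor ligands and receptors, cholesterol synthesis, hypoxia and glycolysis, mitochondrially encoded transcripts, and markers of melanocytes, fibroblasts and leukocytes. Lists were tested by camera (limma 3.58.1) on voom values with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists within a comparison, and members were counted from the edgeR tests adjusted over all genes and over the list alone. Of 231 list tests 85 passed with the preset correlation and 11 with both. Genes were named by rule: S100A8, S100A9, IL6, CXCL8, IL1B, TSLP, TNF, CD44, TLR2, TLR4, HAS2 and HAS3 in each comparison, the 5 highest and 5 lowest changed genes with a mean of at least 5 CPM in the higher group and no overlap between the groups, the 2 most changed members of each list with 3 or more passing, and the 3 smallest p-values where no gene passed. Chance gives no overlap for 10% of genes at 3 against 3 libraries. In the interactions the highest group mean had to reach 5 CPM and overlap was not considered, and genes known only by a clone name were counted but not named.

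The alternatives were RLE scaling in edgeR, DESeq2 1.42.0, no filter on low counts, a filter of mean CPM 5, a replicate block, uniquely mapped reads, exon reads, only the compared groups in the fit, leaving out each library in turn, and, for lists, the estimated correlation and the block. Offsets for GC content and transcript length per library were added after the data were seen, with sequence taken from GRCh38 transcripts matched by gene, which covered 18600 of the tested genes (96.6%). Overlaps of calls were set beside the overlap of independent lists and beside 20 simulations in which no group changed, UVB included. Control libraries stayed shared in the simulations, and each gene was drawn independently, so trends across genes within a library were absent from them. Counts were also made in other splits of the libraries, 10 for 3 against 3 and 100 drawn for the interactions. The steps were tested on simulated data with dispersions from a first fit of the real data. Each gene had the same dispersion in every group, so the simulations do not show how the fit behaves where groups differ in spread. Of 50 genes simulated at each size, edgeR called 31 at a log2 change of 0.25, 46 at 0.5 and all 50 at 1 and at 2, 14 of 191 calls (7.33%) were unchanged genes, and a comparison without changes had 0 calls. In simulated data of the same kind camera found the list raised by 0.5 and called 0 other lists. Genes were drawn independently there, so this does not test the preset correlation on lists whose genes vary together. GC offsets took a simulated GC trend from a Spearman correlation of 0.966 to 0.0138 and from 8714 calls to 0. The gene span test gave -0.735 for a simulated slope and -0.00295 without changes, and the overlap step found 50 of 50 shared genes.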

Results

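Gene expression was measured by poly(A) RNA sequencing in 18 libraries of HaCaT cells, a spontaneously immortalised line of human keratinocytes. The libraries fell into 6 groups of 3: untreated cells, cells given ultra-low molecular weight hyaluronan (uLMW-HA), cells given high molecular weight hyaluronan (HMW-HA), cells irradiated with UVB, and cells given uLMW-HA or HMW-HA after UVB. Hyaluronan (HA) is a sugar polymer of the extracellular matrix whose chains vary widely in length. Total gene reads per library (M, units of 1e6 reads) ranged from 25.7 to 28.5M in untreated cells, 24.8 to 31.4M with uLMW-HA, 27.2 to 43.2M with HMW-HA, 29.1 to 32.6M after UVB, 28.7 to 30.8M with uLMW-HA after UVB and 29.8 to 37.9M with HMW-HA after UVB. Mitochondrial transcripts took 6.97% ± 0.315 of the reads in untreated cells (SD, n = 3), 6.08% ± 0.309 with uLMW-HA, 6.38% ± 0.773 with HMW-HA, 5.67% ± 0.617 after UVB, 5.37% ± 0.0239 with uLMW-HA after UVB and 5.92% ± 0.514 with HMW-HA after UVB. UVB separated the libraries along the first principal component, which held 49.4% of the variance. The second held 5.27%, and along it the HMW-HA libraries without UVB were spread widely, at 36.1, 19.2 and -2.62. Along the third, with 4.91%, UVB replicate 1 lay apart at -34.8. Nothing in the labels states that the replicates are separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

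**Figure D1:**
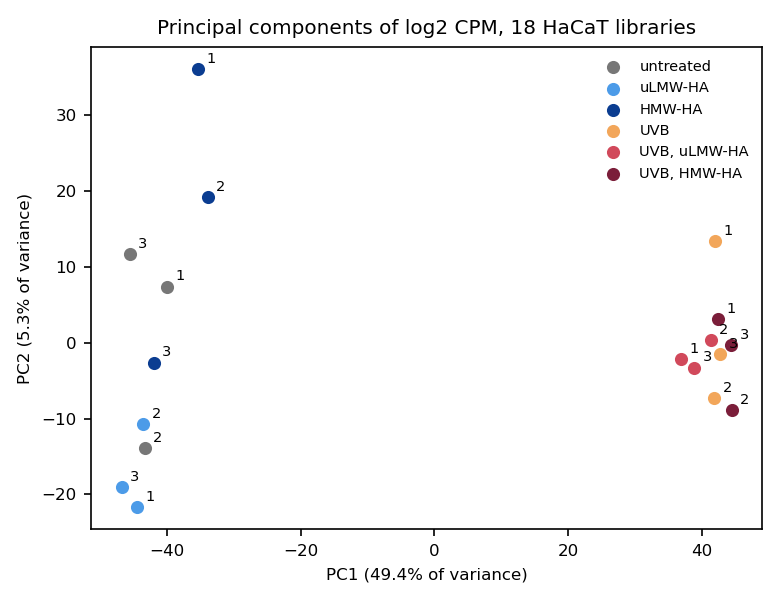
Principal components of the log2 CPM of the 18 libraries, one numbered point per library, coloured by group. The 9 libraries with UVB and the 9 without it lie apart on the first component, which holds 49.4% of the variance.

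UVB alone was compared with no treatment to describe the response against which the HAs were tested. Transcripts of both calprotectin subunits rose: S100A8 (chromosome 1, 153362508 to 153363664, GRCh37) went from 5.36 ± 0.967 to 11.5 ± 0.810 CPM (SD, n = 3 per group), 2.15-fold higher. S100A9 (chromosome 1, 153330330 to 153333503) went from 23.7 ± 3.14 to 44.7 ± 1.30 CPM, 1.89-fold higher. Calprotectin is a calcium-binding alarmin that signals through pattern receptors. The cytokine IL6 was 3.86-fold higher, the neutrophil attractant IL8 (CXCL8) 6.05-fold higher and the cytokine IL1B 2.44-fold higher. The largest increases among genes with a mean of at least 5 CPM and no overlap between the groups were in the interferon-induced genes IFI44L, IFI6 and MX2, at 93.0-, 67.4- and 57.5-fold, and in PDZK1IP1, a membrane protein of epithelia, at 68.7-fold. These folds rest on untreated levels near 0 (0.113, 0.323 and 0.0910 CPM for IFI44L, MX2 and PDZK1IP1), and without untreated replicate 1 the log2 changes of these 3 genes moved from 6.54, 5.84 and 6.10 to 7.12, 6.60 and 6.73. The largest decreases within the same limits were in FOXJ1, the regulator of motile cilia, 10.2-fold lower, and SCGB1A1, a secreted protein of airway club cells, 9.23-fold lower (from 1157 to 125 CPM). Next came the secreted phospholipase PLA2G2A (6.77-fold lower), CD200R1L of the CD200 receptor family (6.54-fold lower) and the selenium-binding protein SELENBP1 (6.39-fold lower). Among receptors and enzymes of hyaluronan, the synthase HAS3 was 2.38-fold higher, TLR2 1.87-fold and TLR4 3.45-fold higher and the receptor CD44 1.10-fold higher, while the synthase HAS2 differed by -0.03 on the log2 scale (SE 0.15, edgeR adjusted p = 0.871). TNF rose by 3.06 on the log2 scale (SE 0.65) from 0.0764 CPM, a few reads per library. TSLP, with 0 to 3 reads per library, was not tested. By the edgeR quasi-likelihood test, 10671 of 19254 genes changed, 5658 higher and 5013 lower, among them 1291 higher and 756 lower by at least 2-fold. The log2 changes of S100A8 and S100A9 were 1.10 (SE 0.15, edgeR adjusted p = 2.65e-06) and 0.92 (SE 0.08, edgeR adjusted p = 2.04e-09), and for both genes all 3 UVB libraries lay above all 3 untreated ones. The non-coding MIRLET7DHG also met the rule at 4.53 (SE 1.70), but its call was lost without any 1 of the 6 libraries (edgeR adjusted p = 0.0553 to 0.101, over all settings 4.13e-10 to 0.429) and its change was -0.51 in uniquely mapped reads and 6.99 in exon reads. Ranges over all settings include DESeq2, here and below.

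**Figure D2:**
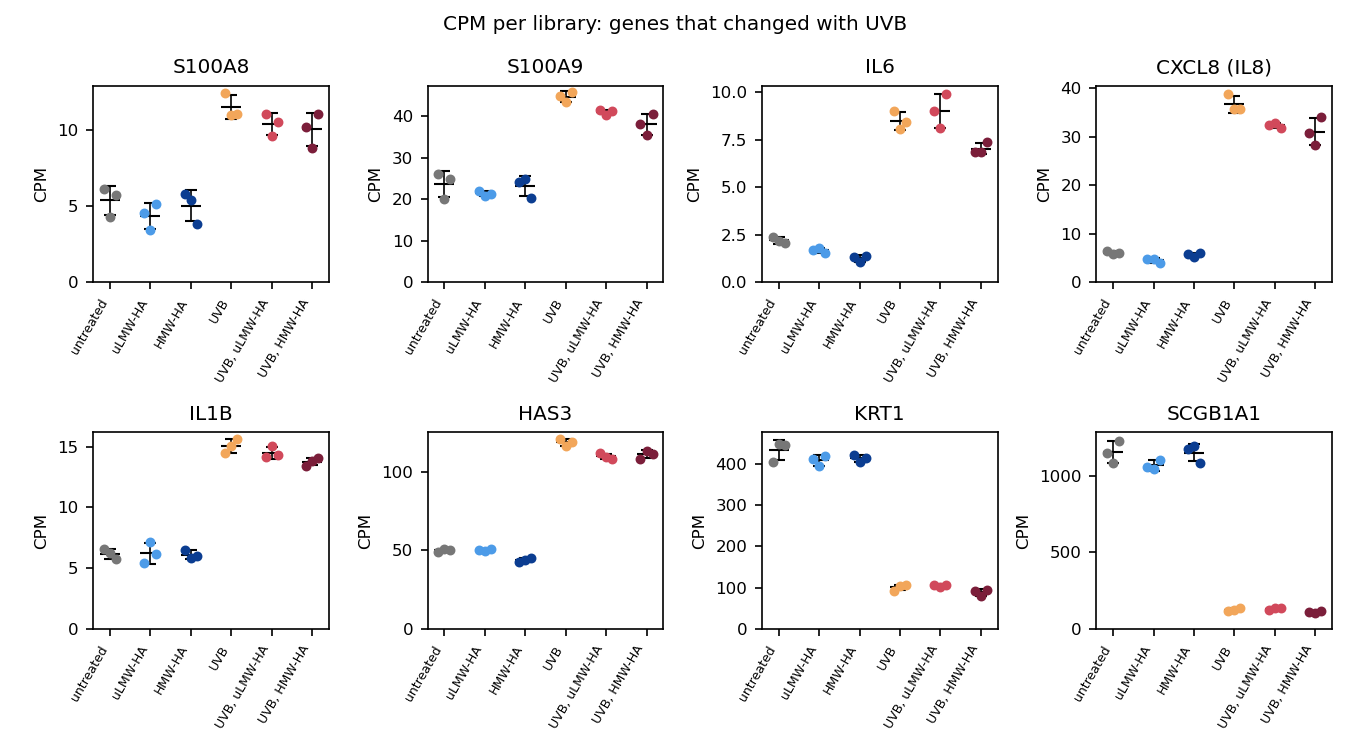
CPM of 8 genes in each of the 18 libraries by group, with the mean and SD of each group. S100A8 and S100A9 are higher in every library with UVB than in every library without it, with or without HA.

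Several gene groups moved together after UVB. All 22 interferon-stimulated genes rose, with a median log2 change of 1.93 (camera adjusted p = 1.14e-18; adjusted p = 0.0796 with an estimated correlation). Of 17 inflammatory cytokines and chemokines tested 14 rose and none fell, led by the chemokines CXCL5 (14.8-fold) and CCL5 (12.8-fold), and this group passed with both correlations (camera adjusted p = 2.76e-06; adjusted p = 0.0380 with an estimated correlation). All 20 mitotic genes rose, among them the kinase CDK1 (3.04-fold) and the chromosomal passenger protein BIRC5 (2.89-fold), with a camera adjusted p = 1.44e-16 (adjusted p = 0.0796 with an estimated correlation). All 20 DNA replication genes rose too, led by the ribonucleotide reductase subunit RRM2 (4.73-fold) and the licensing factor CDC6 (4.0-fold), with a camera adjusted p = 9.52e-16 (adjusted p = 0.0774 with an estimated correlation). Of 16 NF-kappaB feedback targets 10 rose and 2 fell (10 and 3 adjusted over the list alone), including the inhibitors TNFAIP3 (2.90-fold) and BIRC3 (2.26-fold), with a camera adjusted p = 0.0175 (adjusted p = 0.178 with an estimated correlation). Of 16 NRF2 oxidative stress targets 11 rose and 2 fell, led by the cystine transporter SLC7A11 (2.53-fold) and the glutathione synthesis subunit GCLM (1.62-fold), with a camera adjusted p = 0.0290 (adjusted p = 0.174 with an estimated correlation). Of 15 genes of hyaluronan synthesis, breakdown and receptors 9 rose and 2 fell, with the hyaluronan-depolymerising factor KIAA1199 (CEMIP) 2.72-fold higher (log2 1.44, but 2.10 in exon reads) and a camera adjusted p = 0.0175 (adjusted p = 0.0796 with an estimated correlation). Of 13 mitochondrially encoded transcripts 10 fell and none rose, with MT-CYB 1.70-fold and MT-ND3 1.55-fold lower and a camera adjusted p = 0.000743 (adjusted p = 0.592 with an estimated correlation). Unless given, here and in the list counts that follow, counts adjusted over the list alone were the same as those over all genes.

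**Figure D3:**
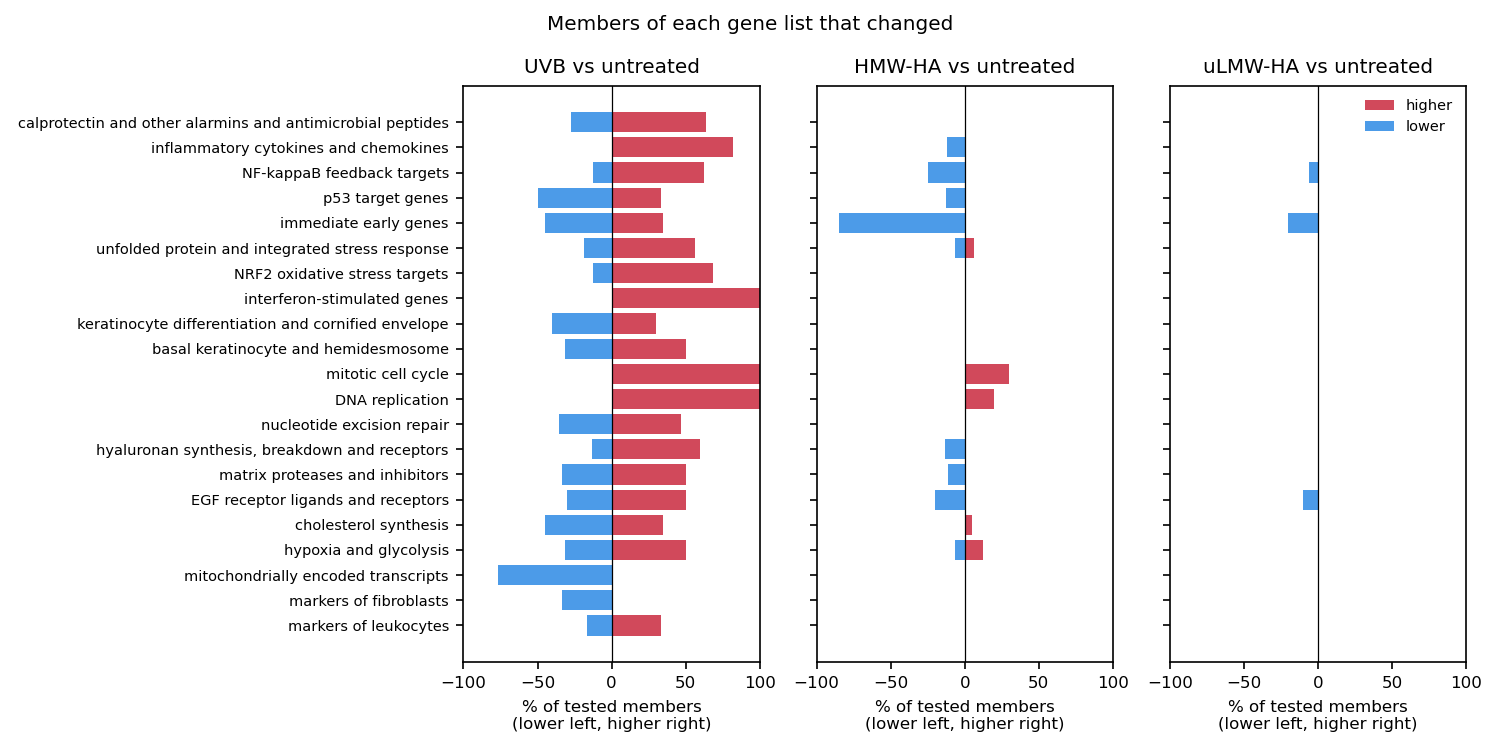
Percent of each list's tested members that passed the edgeR threshold for UVB, HMW-HA and uLMW-HA against untreated cells, higher to the right and lower to the left of 0. All 20 mitotic genes, all 20 replication genes and all 22 interferon-stimulated genes are higher after UVB, and 17 of 20 immediate early genes are lower with HMW-HA than without it.

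Other groups split after UVB. The alarmin and antimicrobial list had 7 of 11 members higher and 3 lower (camera adjusted p = 0.137), with the epidermal cytokine IL1A 5.82-fold higher. IL33, another cytokine of barrier tissue, was called at 1.26 (SE 0.51) but not without untreated replicate 1, 2 or 3 or UVB replicate 1 (edgeR adjusted p = 0.120, 0.103, 0.0510 and 0.169, over all settings 0.0287 to 0.169). Of 24 p53 targets 8 rose, such as the nuclease AEN (2.85-fold), and 12 fell, such as TP53INP1 (2.26-fold lower), with 9 and 12 adjusted over the list alone and a camera adjusted p = 0.392. Of 20 immediate early genes 7 rose, led by the AP-1 subunit FOSL1 (3.05-fold) and the ERK phosphatase DUSP6 (2.73-fold), and 9 fell (camera adjusted p = 0.392). The unfolded protein and integrated stress response had 9 genes higher, including the serine synthesis enzyme PSAT1 (3.57-fold) and the glutathione-degrading CHAC1 (3.46-fold), and 3 lower of 16 (camera adjusted p = 0.137). Among differentiation genes 6 rose and 8 of 20 fell, with the suprabasal keratin KRT1 4.33-fold lower (camera adjusted p = 0.365), while the cornified envelope gene SPRR2D was called higher but stayed under 1 CPM and shares sequence with its family. Basal and hemidesmosome genes split 8 higher and 5 lower of 16, with the keratin KRT15 2.96-fold lower and the laminin chain LAMA3 2.06-fold higher (camera adjusted p = 0.479). Nucleotide excision repair split 8 and 6 of 17 (camera adjusted p = 0.943), with the damage verifier XPA 1.63-fold lower and the ligase LIG1 1.58-fold higher. Matrix proteases and inhibitors split 9 and 6 of 18 (camera adjusted p = 0.365), with fibronectin, FN1, 9.45-fold and the protease inhibitor SERPINE2 4.10-fold higher. EGF receptor ligands and receptors split 5 and 3 of 10 (6 and 3 adjusted over the list alone; camera adjusted p = 0.396), with the ligands AREG and EREG 4.89- and 3.06-fold higher. Cholesterol synthesis had 7 genes higher and 9 lower of 20 (camera adjusted p = 0.339), with the sterol sensor partner INSIG1 1.93-fold lower and the epoxidase SQLE 1.41-fold higher. Hypoxia and glycolysis had 8 higher and 5 lower of 16 (camera adjusted p = 0.216), with the carbonic anhydrase CA9 3.78-fold and the mitophagy receptor BNIP3 3.04-fold higher.

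Markers of other cell types were compared after UVB as well. Of 6 fibroblast markers tested 2 were lower and 0 higher (camera adjusted p = 0.218). Of 6 leukocyte markers 2 were higher and 1 lower, with a median log2 change of 0.01 but a mean of -0.11 and a camera direction of higher (adjusted p = 0.558); the antigen-presentation chaperone CD74, which keratinocytes can also express, was 1.57-fold higher. CSF1R, a macrophage receptor, differed by -1.01 (SE 0.31) at about 1 CPM, but by 1.34 in exon reads, and its call was lost without untreated replicate 3 (edgeR adjusted p = 0.0662) or UVB replicate 2 (edgeR adjusted p = 0.0522, over all settings 0.00317 to 0.0662). Only 2 of 8 melanocyte markers had enough reads, so the list was not tested: MITF, a regulator of pigment cells, rose by 0.80 (SE 0.07), and PMEL differed by -0.13 (SE 0.12, edgeR adjusted p = 0.398).

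HMW-HA alone was compared with no treatment to ask what the long polymer does to unstressed cells. Immediate early genes, the first to be transcribed after growth factor or stress signals, were lower: 17 of 20 fell and none rose (18 lower adjusted over the list alone). The AP-1 subunit FOSB (chromosome 19, 45971253 to 45978437, GRCh37) dropped from 111 ± 9.84 to 9.75 ± 0.1 CPM (SD, n = 3 per group), 11.4-fold lower, the stress factor ATF3 from 55.7 ± 0.459 to 12.6 ± 1.17 CPM, and FOS from 368 ± 16.2 to 101 ± 6.30 CPM. The zinc finger factor EGR3 was 3.42-fold lower. Outside this list, the nuclear receptor NR4A1 dropped from 104 ± 7.24 to 21.2 ± 0.676 CPM. Of 16 NF-kappaB feedback targets 4 fell (6 adjusted over the list alone), among them BCL3 (1.42-fold lower) and the inhibitor NFKBIA (1.18-fold lower). Of 24 p53 targets 3 fell (1 higher and 4 lower adjusted over the list alone), among them the kinase PLK3 (1.47-fold lower) and BTG2 (1.35-fold lower), with a camera adjusted p = 0.0134 (adjusted p = 0.109 with an estimated correlation). Of the mitotic genes 6 of 20 rose (15 adjusted over the list alone), such as CCNB1 and BIRC5, each 1.24-fold, with a camera adjusted p = 2.34e-14 (adjusted p = 0.109 with an estimated correlation). Of the replication genes 4 of 20 rose (15 adjusted over the list alone), such as CDC6 and RRM2, each 1.28-fold, with a camera adjusted p = 2.52e-09 (adjusted p = 0.109 with an estimated correlation). Both calprotectin genes were close to untreated, with log2 differences of -0.09 for S100A8 (SE 0.16, edgeR adjusted p = 0.874) and -0.02 for S100A9 (SE 0.08, edgeR adjusted p = 0.940). The edgeR test called 266 genes, 96 higher and 170 lower, with FOSB at a log2 change of -3.51 (SE 0.09, edgeR adjusted p = 1.96e-14). The immediate early list passed with both correlations (camera adjusted p = 4.78e-62; adjusted p = 0.000123 with an estimated correlation), as did the NF-kappaB list (camera adjusted p = 4.98e-06; adjusted p = 0.0320 with an estimated correlation). Mitochondrially encoded transcripts were lower (0 of 13 past the threshold, camera adjusted p = 0.000161, adjusted p = 0.436 with an estimated correlation). EGF receptor ligands and receptors were lower (0 higher and 2 lower of 10, camera adjusted p = 0.000624, adjusted p = 0.0651 with an estimated correlation). Matrix proteases and inhibitors were lower (0 higher and 2 lower of 18, camera adjusted p = 0.0134, adjusted p = 0.317 with an estimated correlation). The count and its split depended on the libraries: 128 genes (21 higher and 107 lower) without untreated replicate 2 and 138 (27 and 111) without replicate 3. Without HMW-HA replicate 1 it was 142 (26 and 116), without replicate 2 it was 123 (18 and 105), and without replicate 3 it was 1648 (1007 and 641), mostly higher. With only the compared groups it was 74 (4 and 70), with DESeq2 403 (143 and 260), with a filter of mean CPM 5 it was 406 (179 and 227) and with no filter 539 (302 and 237). HMW-HA libraries without UVB differed most within their group (chi-square per gene 8.08 to 20.3, at most 7.66 in other groups). The fit of all 6 groups may understate that spread, which was not tested.

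**Figure D4:**
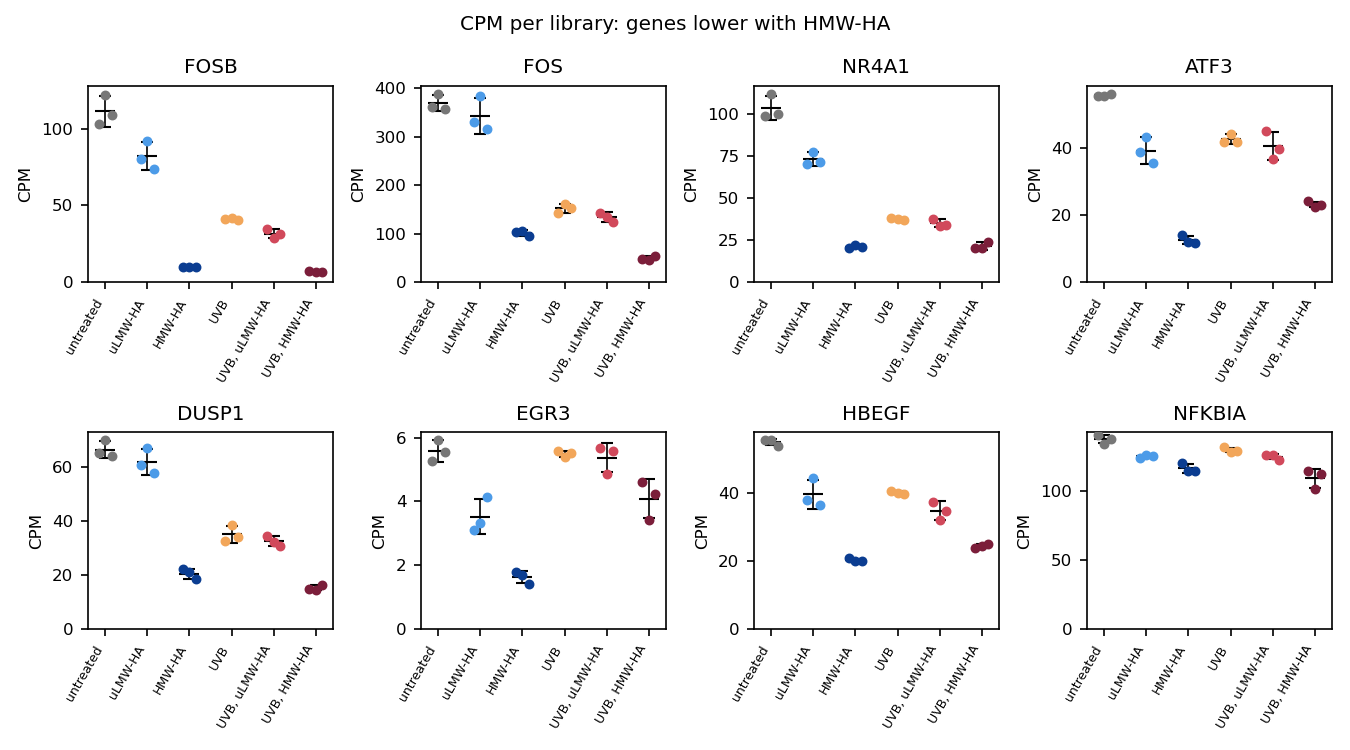
CPM of 8 genes that are lower with HMW-HA, in each of the 18 libraries by group, with the mean and SD of each group. FOSB is lower in the 3 HMW-HA libraries (mean 9.75 CPM) than in the untreated ones (mean 111 CPM), and after UVB it is lower with HMW-HA (mean 6.96 CPM) than without it (mean 41.0 CPM).

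Other changes with HMW-HA were in single genes, and the cytokine and hyaluronan lists did not pass (camera adjusted p = 0.0794 and 0.531). IL6 was 1.77-fold lower (log2 -0.83, SE 0.15, edgeR adjusted p = 0.00243), and the hyaluronan synthase HAS3 was 1.14-fold lower (edgeR adjusted p = 0.00481). KREMEN2, C9orf40, the replication kinase CDC7, PLEKHO2 and the ETS factor ETV4 were the 5 highest genes with a mean of at least 5 CPM and no overlap between the groups, 1.53-, 1.48-, 1.39-, 1.38- and 1.38-fold higher. CA9 was 1.62-fold higher and the vascular growth factor VEGFA 1.26-fold lower. IL8, IL1B, TNF, CD44, TLR2, TLR4 and HAS2 did not pass, with log2 differences between -0.80 and 0.31. That of TNF, which had a few reads, moved from -4.29 without HMW-HA replicate 3 to -0.07 without replicate 2. With only the compared groups in the fit, the calls of IL6, HAS3, KREMEN2, C9orf40, CDC7, PLEKHO2, ETV4, CCNB1, BIRC5, CDC6, RRM2 and CA9 were lost (edgeR adjusted p = 0.0607 to 0.275, over all settings of these genes 7.47e-10 to 0.275). Calls were also lost for IL6 without HMW-HA replicate 2 (edgeR adjusted p = 0.0573), CDC6 without untreated replicate 3 (edgeR adjusted p = 0.0542), and CDC7, PLEKHO2, ETV4, CCNB1, BIRC5 or CA9 without 1 or another of untreated replicates 1, 2 and 3 and HMW-HA replicates 1 and 2 (edgeR adjusted p = 0.0567 to 0.198).

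uLMW-HA alone was compared with no treatment for the same question about short chains. The stress factor ATF3 was 1.42-fold lower (55.7 ± 0.459 against 39.2 ± 3.98 CPM; SD, n = 3 per group), the nuclear receptor NR4A1 1.42-fold lower and the EGF receptor ligand HBEGF 1.39-fold lower. EGR3 and FOSB were 1.60- and 1.35-fold lower, and SCD, the stearoyl-CoA desaturase, was the 1 gene called higher in this test, 1.14-fold. Of 20 immediate early genes 4 fell (7 adjusted over the list alone), and the list was lower with a camera adjusted p = 8.11e-11 (adjusted p = 0.170 with an estimated correlation). No member of the mitochondrially encoded list passed alone, but its median log2 difference was -0.22 and the list was lower with a camera adjusted p = 5.15e-10 (adjusted p = 0.314 with an estimated correlation), as the share of mitochondrial reads was. Other lists also passed with the preset correlation only. Replication genes were lower (0 of 20 past the threshold, camera adjusted p = 6.89e-05, adjusted p = 0.328 with an estimated correlation). Mitotic genes were lower (0 of 20 past the threshold, 0 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.00235, adjusted p = 0.478 with an estimated correlation). Cytokines and chemokines were lower (0 of 17 past the threshold, 0 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.00467, adjusted p = 0.202 with an estimated correlation). NF-kappaB feedback targets were lower (0 higher and 1 lower of 16, 0 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.0446, adjusted p = 0.328 with an estimated correlation). Differentiation genes were lower (0 of 20 past the threshold, 0 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0446, adjusted p = 0.328 with an estimated correlation). Cholesterol synthesis genes were higher (0 of 20 past the threshold, 3 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.00508, adjusted p = 0.314 with an estimated correlation). Basal keratinocyte genes were higher (0 of 16 past the threshold, 1 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.0251, adjusted p = 0.404 with an estimated correlation). The alarmin list (0 lower, 2 adjusted over the list alone) was lower with a camera adjusted p = 6.89e-05 (adjusted p = 0.202 with an estimated correlation). S100A8 differed by -0.31 (SE 0.17, edgeR adjusted p = 0.535), S100A9 by -0.14 (SE 0.08, edgeR adjusted p = 0.549), IL8 by -0.42 (SE 0.11, edgeR adjusted p = 0.224) and IL6 by -0.39 (SE 0.14, edgeR adjusted p = 0.422). IL8 passed with no filter on low counts (edgeR and DESeq2 adjusted p from 0.0115 to 0.734 over all settings). In all, 11 genes passed by edgeR, 1 higher and 10 lower, with NR4A1 and HBEGF at an edgeR adjusted p = 0.000417 and ATF3 at 0.00204. With DESeq2 39 genes passed (12 higher and 27 lower) and with no filter on low counts 164 (102 higher and 62 lower), mostly higher. The count was 5, 4 and 4 without untreated replicates 1, 2 and 3, and 4 and 6 without uLMW-HA replicates 1 and 3. SCD lost its call without any 1 of the 6 libraries (edgeR adjusted p = 0.0657 to 0.431), EGR3 without any but uLMW-HA replicate 3 (0.126 to 0.439), and FOSB without untreated replicate 2 or 3 or uLMW-HA replicate 1 or 3 (0.0865 to 0.201). Over all settings the edgeR and DESeq2 adjusted p ranged from 0.000165 to 0.431 for SCD, 0.00134 to 0.439 for EGR3 and 1.76e-15 to 0.252 for FOSB, whose highest value came with only the compared groups.

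HMW-HA after UVB was compared with UVB alone to ask whether it dampens the inflammatory response. FOSB was 5.88-fold lower (41.0 ± 0.636 against 6.96 ± 0.229 CPM; SD, n = 3 per group), FOS 3.07-fold, the MAP kinase phosphatase DUSP1 2.30-fold, ATF3 1.84-fold and, outside the immediate early list, NR4A1 1.75-fold lower. Of 20 immediate early genes 8 fell and none rose (14 lower adjusted over the list alone), and of 16 NF-kappaB feedback targets 3 fell (4 adjusted over the list alone), including NFKBIA (1.19-fold lower) and TNFAIP3 (1.31-fold lower). The cytokine and chemokine list was lower as a whole, although 0 members passed over all genes and 2 adjusted over the list alone. The alarmin list was lower with a median of -0.14 (0 members past the threshold, 2 adjusted over the list alone; camera adjusted p = 0.00690; adjusted p = 0.268 with an estimated correlation). Of its calprotectin genes neither passed in the test used here: S100A8 differed by -0.19 (SE 0.13, 95% interval -0.47 to 0.08, edgeR adjusted p = 0.937) and S100A9 by -0.23 (SE 0.07, 95% interval -0.38 to -0.08, edgeR adjusted p = 0.554). S100A9 did pass as lower under 2 alternatives, with no filter on low counts (log2 -0.21) and with GC and length offsets (log2 -0.26), and its edgeR and DESeq2 adjusted p ran from 0.0154 to 0.864 over all settings. IL6 differed by -0.27 (SE 0.10, edgeR adjusted p = 0.721) and IL8 by -0.24 (SE 0.06, edgeR adjusted p = 0.238). IL8 passed as lower with GC and length offsets (edgeR and DESeq2 adjusted p from 0.0190 to 0.814 over all settings), while IL6, IL1B, TNF, CD44, TLR2, TLR4, HAS2 and HAS3 did not pass. GBP6, an interferon-induced GTPase, was the 1 gene called higher in this test, 1.29-fold. The interferon-stimulated list was lower with a median of -0.11 (camera adjusted p = 2.20e-10; adjusted p = 0.214 with an estimated correlation). The mitotic list was higher with a median of 0.08 (camera adjusted p = 2.18e-06; adjusted p = 0.283 with an estimated correlation). p53 targets were lower (0 of 24 past the threshold, 0 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.00928, adjusted p = 0.139 with an estimated correlation). Hypoxia and glycolysis genes were lower (0 of 16 past the threshold, 0 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.00507, adjusted p = 0.214 with an estimated correlation). Replication genes were higher (0 of 20 past the threshold, camera adjusted p = 0.00775, adjusted p = 0.471 with an estimated correlation). The edgeR test called 26 genes, 25 of them lower. It called 70 with no filter (11 higher and 59 lower), 59 with GC and length offsets (2 and 57) and 42 with a filter of mean CPM 5 (1 and 41), and DESeq2 called 52 (3 and 49). The immediate early list (camera adjusted p = 1.40e-37; adjusted p = 0.00126 with an estimated correlation), the NF-kappaB list (camera adjusted p = 5.66e-05; adjusted p = 0.0458 with an estimated correlation) and the cytokine list (camera adjusted p = 9.09e-07; adjusted p = 0.0127 with an estimated correlation) passed with both correlations. GBP6 lost its call without UVB replicate 1 or 3 or HMW-HA after UVB replicate 2 (edgeR adjusted p = 0.0852, 0.101 and 0.116, over all settings 0.000982 to 0.116). TNFAIP3 lost its call without UVB replicate 1 or 2 or HMW-HA after UVB replicate 1 (edgeR adjusted p = 0.0576, 0.0792 and 0.1, from 7.05e-08 upwards over all settings). The labels do not make clear that UVB alone was given at the dose stated for the HA groups.

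uLMW-HA after UVB was compared with UVB alone for the same question. S100A8 stood at 10.4 ± 0.738 CPM with uLMW-HA and 11.5 ± 0.810 CPM without it (SD, n = 3 per group), and S100A9 at 41.0 ± 0.570 and 44.7 ± 1.30 CPM. The log2 differences were -0.15 (95% interval -0.42 to 0.13, edgeR adjusted p = 0.985) and -0.12 (95% interval -0.27 to 0.02, edgeR adjusted p = 0.983). IL8 differed by -0.18 (SE 0.06), IL6 by 0.09 (SE 0.10) and IL1B by -0.05 (SE 0.07), and none of these or of the receptors and synthases of hyaluronan passed. The smallest p-values belonged to 1 pseudogene known only by a clone name, to MAFA, a transcription factor best known in pancreatic beta cells (log2 0.33, SE 0.06, edgeR adjusted p = 0.421), and to FLJ27365 (log2 0.25, SE 0.06, edgeR adjusted p = 0.712). MAFA and FLJ27365 passed with no filter on low counts (edgeR and DESeq2 adjusted p from 0.0270 and 0.0132 up to 1 over all settings). As groups, alarmins were lower with a median of -0.11 (camera adjusted p = 0.0309; adjusted p = 0.405 with an estimated correlation). Interferon-stimulated genes were lower with a median of -0.08 (camera adjusted p = 2.43e-07; adjusted p = 0.319 with an estimated correlation), and cytokines and chemokines with a median of -0.09 (camera adjusted p = 0.00135; adjusted p = 0.161 with an estimated correlation). Basal keratinocyte genes were higher with a median of 0.06 (camera adjusted p = 0.000929; adjusted p = 0.267 with an estimated correlation), as were fibroblast markers, most of which had few reads, with a median of 0.35 (camera adjusted p = 0.0245; adjusted p = 0.161 with an estimated correlation). In these lists 0 members passed over all genes, and 1 alarmin and 1 interferon-stimulated gene passed adjusted over the list alone. Replication genes were lower (0 of 20 past the threshold, camera adjusted p = 0.0180, adjusted p = 0.541 with an estimated correlation). EGF receptor ligands and receptors were lower (0 of 10 past the threshold, 0 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0309, adjusted p = 0.267 with an estimated correlation). The edgeR test called 0 of 19254 genes, 911 had an unadjusted p under 0.05, and DESeq2 called 3. By edgeR there were 24 with no filter (17 higher and 7 lower) and 5 with only the compared groups (4 and 1). Without UVB replicate 3 edgeR called 1 gene.

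The overlap of calls addressed whether HA reversed UVB changes. Of the 26 genes called with HMW-HA after UVB, 22 were also called with UVB. Of these, 8 were higher with UVB and lower with HMW-HA, while the rest of the 22 moved in the same direction in both. The 8 were the RNase ZC3H12A and the deubiquitinase TNFAIP3, both brakes on NF-kappaB signalling, the NF-kappaB cofactor NFKBIZ, the phosphatase DUSP2, the kinase SGK1, CD74, KLF4 and FOSL1. Independent lists would share 7.61 genes in opposite directions. In 20 simulations where no group changed, UVB included, the overlap was 0 each time. That 0 says nothing about the 8, since such groups give few calls to share. With the UVB effect taken from the uLMW-HA arm, which shares no library, the overlap was 9 genes against 7.54 for independent lists. With DESeq2, which called 52 genes with HMW-HA after UVB against 26, these overlaps were 21 and 20. The overlap of independent lists was not computed for DESeq2, so its larger overlaps do not show more reversal. For uLMW-HA after UVB the edgeR overlap was 0, since no gene was called, and 1 with DESeq2. Without UVB, ATF3, NR4A1, HBEGF, FOSB, EGR3, DUSP4, DUSP5, SIK1, RND3 and IRF1 were lower with each HA than in untreated cells. These were 10 genes against 0.0933 for independent lists. Part of this may come from the shared untreated libraries, and the 0 shared in the simulations, which give few calls, does not settle it. With uLMW-HA without UVB set against HMW-HA after UVB, which share no library but differ in UVB and have fewer calls, 5 genes fell in both. The reverse pairing, uLMW-HA after UVB with HMW-HA without it, shared 0, since edgeR called no gene for the former. With HMW-HA 23 genes were lower both with and without UVB, against 0.226 for independent lists, with no library in common. With DESeq2 the overlaps of 10, 5, 0 and 23 genes were 18, 11, 1 and 39, again without a value for independent lists.

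uLMW-HA and HMW-HA were compared directly without UVB, which addresses chain length. Immediate early genes were higher with uLMW-HA: FOSB was 8.43-fold higher (82.0 ± 9.23 against 9.75 ± 0.1 CPM; SD, n = 3 per group), FOS 3.38-fold, ATF3 3.13-fold and DUSP1 3.03-fold, and 16 of 20 members rose (17 adjusted over the list alone). NR4A1, outside this list, was 3.45-fold higher. Of 20 mitotic genes 17 were lower with uLMW-HA, such as BIRC5 (1.47-fold lower) and the kinase AURKB (1.35-fold lower), with a camera adjusted p = 6.30e-14 (adjusted p = 0.153 with an estimated correlation). Of 20 replication genes 16 were lower, such as CDC6 (1.36-fold lower) and RRM2 (1.33-fold lower), with a camera adjusted p = 2.68e-12 (adjusted p = 0.106 with an estimated correlation). The lowest genes with a mean of at least 5 CPM and no overlap between the groups were the non-coding BCYRN1, whose copies share sequence (1.76-fold lower), the activin antagonist FST (1.68-fold lower), the chloride transporter SLC26A3 (1.62-fold lower), the cohesion factor DSCC1 (1.55-fold lower) and the mitochondrial import subunit TOMM6 (1.5-fold lower). HAS3 was 1.14-fold higher with uLMW-HA (log2 0.20, SE 0.04, edgeR adjusted p = 0.00218). BCL3, PLK3, BTG2 and the stress phosphatase subunit PPP1R15A were 1.25-, 1.31-, 1.30- and 1.37-fold higher. The log2 difference was -0.22 for S100A8 (edgeR adjusted p = 0.433) and -0.12 for S100A9 (edgeR adjusted p = 0.381). IL6 differed by 0.44 (SE 0.15, edgeR adjusted p = 0.0738) and passed with GC and length offsets or without HMW-HA replicate 3 (edgeR and DESeq2 adjusted p from 0.0412 to 0.430 over all settings). IL8 differed by -0.30 (SE 0.10, edgeR adjusted p = 0.0596) and passed with no filter, with mean CPM 5 and with DESeq2 (edgeR and DESeq2 adjusted p from 0.0358 to 0.242 over all settings). Across all genes 2333 were called by edgeR, 960 higher and 1373 lower with uLMW-HA. With only the compared groups in the fit it was 354, with 195 higher and 159 lower. The immediate early list passed with both correlations (camera adjusted p = 2.50e-27; adjusted p = 0.00546 with an estimated correlation). EGF receptor ligands and receptors were higher (2 higher and 0 lower of 10, 4 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.000560, adjusted p = 0.0840 with an estimated correlation). NF-kappaB feedback targets were higher (3 higher and 0 lower of 16, 5 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.0365, adjusted p = 0.299 with an estimated correlation). Basal keratinocyte genes were higher (5 higher and 1 lower of 16, 6 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.0454, adjusted p = 0.724 with an estimated correlation). The count was 676 and 874 without uLMW-HA replicates 1 and 3 and 744, 397 and 4202 without HMW-HA replicates 1, 2 and 3. Of the lowest genes, FST lost its call without any library but HMW-HA replicate 3 (edgeR adjusted p = 0.0628 to 0.169, over all settings 0.00681 to 0.169), and SLC26A3 without uLMW-HA replicate 1 or 3 or HMW-HA replicate 2 (edgeR adjusted p = 0.0676, 0.0532 and 0.0812, over all settings 0.000272 to 0.0812). BCYRN1 lost its call with only the compared groups (edgeR adjusted p = 0.0518, over all settings from 3.51e-14).

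After UVB the same comparison gave fewer calls. FOSB was 4.54-fold higher with uLMW-HA than with HMW-HA (31.6 ± 3.08 against 6.96 ± 0.229 CPM; SD, n = 3 per group), FOS 2.70-fold, DUSP1 2.14-fold, ATF3 1.75-fold and, outside the immediate early list, NR4A1 1.62-fold. Of 20 immediate early genes 8 were higher and none lower (14 and 1 adjusted over the list alone). S100A8 differed by 0.05 (95% interval -0.23 to 0.33, edgeR adjusted p = 0.948) and S100A9 by 0.11 (95% interval -0.04 to 0.25, edgeR adjusted p = 0.683). By edgeR 34 genes passed, 33 higher and 1 lower. With no filter 108 passed (72 higher and 36 lower), with only the compared groups 99 (82 and 17) and with DESeq2 93 (80 and 13). The immediate early list passed with both correlations (camera adjusted p = 2.63e-27; adjusted p = 0.00469 with an estimated correlation). The gene called lower in this test, the ribosome recycling factor ABCE1 (log2 -0.18, SE 0.04), lost its call without any 1 of the 6 libraries (edgeR adjusted p = 0.0661 to 0.25, from 0.0101 upwards over all settings). Other lists passed with the preset correlation only. Mitotic genes were lower (0 of 20 past the threshold, 0 higher and 1 lower adjusted over the list alone, camera adjusted p = 6.48e-07, adjusted p = 0.504 with an estimated correlation). Replication genes were lower (0 of 20 past the threshold, camera adjusted p = 5.31e-06, adjusted p = 0.504 with an estimated correlation). Mitochondrially encoded transcripts were lower (0 of 13 past the threshold, camera adjusted p = 0.00226, adjusted p = 0.511 with an estimated correlation). Basal keratinocyte genes were higher (0 of 16 past the threshold, 4 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0217, adjusted p = 0.504 with an estimated correlation). The count was 15 and 20 without uLMW-HA after UVB replicates 1 and 3 and 17 without HMW-HA after UVB replicate 2.

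The UVB response was also measured within each HA, to ask whether HA changed it. HA was given after irradiation, so each arm compared cells given an HA after UVB with cells given the same HA alone. In the uLMW-HA arm S100A8 was 2.40-fold, S100A9 1.92-fold, IL6 5.36-fold and IL8 7.12-fold higher with UVB. In the HMW-HA arm they were 1.99-, 1.64-, 5.67- and 5.55-fold higher. All 22 interferon-stimulated genes rose in both arms (camera adjusted p = 1.46e-18 and 2.09e-18; adjusted p = 0.0750 and 0.0728 with an estimated correlation), led by IFI6 (43.1-fold with uLMW-HA) and IFI44L (30.9-fold with HMW-HA), and SCGB1A1 was 8.16-fold lower with uLMW-HA and 10.6-fold lower with HMW-HA. UVB changed 10751 genes with uLMW-HA and 10662 with HMW-HA by edgeR. Cytokines and chemokines rose in both, 16 of 17 with uLMW-HA (camera adjusted p = 2.21e-06; adjusted p = 0.0357 with an estimated correlation) and 14 with HMW-HA (camera adjusted p = 2.20e-06; adjusted p = 0.0350 with an estimated correlation). With HMW-HA 13 immediate early genes rose and 6 fell of 20, led by FOSL1 (3.90-fold, log2 1.96, but 2.83 in exon reads; camera adjusted p = 0.0369, adjusted p = 0.534 with an estimated correlation). CD44 did not pass with uLMW-HA (log2 0.08, SE 0.04, edgeR adjusted p = 0.0995), but it passed with only the compared groups and with GC and length offsets (edgeR and DESeq2 adjusted p from 0.000309 to 0.355 over all settings). The pseudogenes CSPG4P10 and CSPG4P11 met the naming rule as lower after UVB with uLMW-HA, but they share reads with near-identical copies.

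Other lists in the UVB response passed with the preset correlation only. All 20 mitotic genes rose in both arms (camera adjusted p = 5.38e-17 with uLMW-HA and 5.87e-16 with HMW-HA; adjusted p = 0.0750 and 0.0728 with an estimated correlation). All 20 replication genes rose in both (camera adjusted p = 3.31e-16 and 1.96e-15; adjusted p = 0.0701 and 0.0728 with an estimated correlation). Of 16 NF-kappaB feedback targets 10 rose and 0 fell with uLMW-HA (10 and 1 adjusted over the list alone) and 11 and 1 with HMW-HA (camera adjusted p = 0.00548 and 0.00139; adjusted p = 0.110 and 0.0728 with an estimated correlation). Of 16 NRF2 targets 10 rose and 3 fell with uLMW-HA and 11 and 3 with HMW-HA (camera adjusted p = 0.0382 and 0.0347; adjusted p = 0.171 and 0.150 with an estimated correlation). Of 15 hyaluronan genes 8 rose and 2 fell with uLMW-HA and 9 and 1 with HMW-HA (camera adjusted p = 0.0199 and 0.0165; adjusted p = 0.0750 and 0.0728 with an estimated correlation). With uLMW-HA 6 of 13 mitochondrially encoded transcripts fell (camera adjusted p = 0.0290; adjusted p = 0.607 with an estimated correlation).

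The interaction tested directly whether the response to HA differed with and without UVB. For HMW-HA immediate early genes passed: the interaction was 1.35 for EGR3 (SE 0.19), 1.27 for ATF3 (SE 0.11) and 0.96 for FOSB (SE 0.14). Outside that list it was 1.48 for NR4A1 (SE 0.09, edgeR adjusted p = 1.06e-08) and 0.74 for HBEGF (SE 0.09), where a positive value means a smaller decrease with HMW-HA after UVB than without it. Of 20 immediate early genes 8 passed (17 adjusted over the list alone), and the list passed with both correlations (camera adjusted p = 2.22e-35; adjusted p = 0.00161 with an estimated correlation). For calprotectin the interaction with HMW-HA was -0.11 for S100A8 (SE 0.21, edgeR adjusted p = 0.938) and -0.20 for S100A9 (SE 0.11, edgeR adjusted p = 0.726), while with uLMW-HA it was 0.16 (SE 0.21, edgeR adjusted p = 0.910) and 0.02 (SE 0.11, edgeR adjusted p = 0.984). The edgeR test called 27 genes for HMW-HA, 25 positive and 2 negative. For HMW-HA the count was 107 with no filter (55 and 52), 42 with DESeq2 (37 and 5) and 15 with only the compared groups, all positive. The test called 0 genes for uLMW-HA (28 with no filter, 18 positive and 10 negative), where 1017 genes had an unadjusted p under 0.05 and DESeq2 called 4. Among genes with a symbol the smallest edgeR adjusted p were 0.335 for the kinase SIK1 (log2 0.29) and 0.713 for IRF1 (log2 0.23). SIK1 passed with no filter, exon reads or DESeq2, and IRF1 with DESeq2 (edgeR and DESeq2 adjusted p from 0.00368 and 0.00754 up to 0.984 over all settings). The negative interaction of UHRF1, a DNA methylation factor (-0.37, SE 0.07), was lost without any 1 of the 12 libraries except untreated replicate 2, HMW-HA replicate 3 and UVB replicate 1 (edgeR adjusted p = 0.0533 to 0.175, over all settings 0.00183 to 0.175). The HMW-HA count was 75 without HMW-HA replicate 3, with 41 positive and 34 negative.

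Some lists had an interaction at the preset correlation but not at the estimated one. The next lists are for HMW-HA. Mitochondrially encoded transcripts had a positive interaction (0 of 13 past the threshold, camera adjusted p = 2.53e-06, adjusted p = 0.344 with an estimated correlation). EGF receptor ligands and receptors had a positive interaction (1 positive and 0 negative of 10, camera adjusted p = 0.00447, adjusted p = 0.228 with an estimated correlation). Matrix proteases and inhibitors had a positive interaction (0 of 18 past the threshold, camera adjusted p = 0.0295, adjusted p = 0.344 with an estimated correlation). Mitotic genes had a negative interaction (0 of 20 past the threshold, camera adjusted p = 1.71e-06, adjusted p = 0.344 with an estimated correlation). Replication genes had a negative interaction (0 of 20 past the threshold, 0 positive and 2 negative adjusted over the list alone, camera adjusted p = 4.84e-06, adjusted p = 0.344 with an estimated correlation). Interferon-stimulated genes had a negative interaction (0 of 22 past the threshold, camera adjusted p = 4.84e-06, adjusted p = 0.344 with an estimated correlation). Hypoxia and glycolysis genes had a negative interaction (0 of 16 past the threshold, 0 positive and 2 negative adjusted over the list alone, camera adjusted p = 0.0295, adjusted p = 0.344 with an estimated correlation). The next are for uLMW-HA, where no gene passed. Immediate early genes had a positive interaction (0 of 20 past the threshold, 3 positive and 0 negative adjusted over the list alone, camera adjusted p = 1.37e-05, adjusted p = 0.493 with an estimated correlation). Mitochondrially encoded transcripts had a positive interaction (0 of 13 past the threshold, camera adjusted p = 0.000199, adjusted p = 0.576 with an estimated correlation). Differentiation genes had a positive interaction (0 of 20 past the threshold, 1 positive and 0 negative adjusted over the list alone, camera adjusted p = 0.00822, adjusted p = 0.493 with an estimated correlation). Alarmins had a positive interaction (0 of 11 past the threshold, camera adjusted p = 0.0388, adjusted p = 0.576 with an estimated correlation). Mitotic genes had a positive interaction (0 of 20 past the threshold, camera adjusted p = 0.0476, adjusted p = 0.607 with an estimated correlation). Replication genes had a positive interaction (0 of 20 past the threshold, camera adjusted p = 0.0476, adjusted p = 0.607 with an estimated correlation). Interferon-stimulated genes had a negative interaction (0 of 22 past the threshold, camera adjusted p = 0.00246, adjusted p = 0.576 with an estimated correlation). Cholesterol synthesis genes had a negative interaction (0 of 20 past the threshold, camera adjusted p = 0.0199, adjusted p = 0.549 with an estimated correlation).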

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

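The test of harvest or medium timing was chosen only after the result was seen, and the offsets for GC content and length were added after the data were seen. The response to HMW-HA differed with and without UVB in 27 genes by the edgeR interaction test, 8 of them immediate early genes (JUN, ATF3, EGR1, EGR3, KLF4, DUSP5, PHLDA1 and FOSB), a difference between groups. With the libraries regrouped, 8 of 100 drawn splits, the real split included, gave at least 27 genes. The highest other split gave 422. A regrouping can leave the effect of HMW-HA itself (266 genes without UVB) uneven between the UVB states, and the interaction test then counts it. These splits therefore cannot decide whether chance or a structure of the samples gave the 27 genes, and neither was excluded. Intronic reads, which the report's comparisons used only within all gene reads, held a signal when tested alone: of 14653 genes tested in them by edgeR, 4079 changed with UVB (2037 higher and 2042 lower, 3385 of them called in the same direction in all gene reads) and 116 with HMW-HA without UVB (19 higher and 97 lower, 34 of them called in the same direction in all gene reads).

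In immediate early genes, 17 of 20 were lower with HMW-HA than in untreated cells. A single library that stands apart is argued against, since at least 16 of the 20 stayed lower and past the threshold whichever of the 6 libraries was left out, and a trend with GC content or transcript length is argued against by the 18 that did so with GC and length offsets. An effect of HMW-HA and a harvest or medium change at another time in the HMW-HA wells cannot be told apart, because in 6 of 6 HMW-HA libraries the mean level of the list lay below every library without HA of the same UVB state, which both predict, and the labels give no times. The median log2 change of intronic reads was -0.497 over 14 of these genes, 11 of them below 0. This lies between the bounds set for and against fewer new transcripts, close to the first. For the list as a whole, these reads thus leave open whether fewer new transcripts were made. In 5 genes intronic reads were lower and past the threshold: FOSB (-5.51), ATF3 (-1.67), DUSP5 (-1.27), KLF4 (-0.66) and FOSL1 (-0.47). Fewer new transcripts of those genes would give this. In EGR1, PHLDA1 and SPRY4 they were not lower (0.15, 0.48 and 0.01). The RNA was poly(A)-selected and strand use is not given. Intronic reads of new transcripts were therefore not separated from those of other RNA or of overlapping genes. An effect of HMW-HA on the immediate early genes stays a hypothesis.

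Between uLMW-HA and HMW-HA without UVB 2333 genes differed, more than the 11 and 266 that differed between either and untreated cells. A trend with GC content or transcript length as the whole source is argued against, since 1801 genes were called with GC and length offsets. Only 1313 of them were among the 2333, so such a trend as part of the source is not excluded. The length trend spanned 0.565 and 0.480 on the log2 scale in uLMW-HA replicates 1 and 3, and 0.482 and 0.488 in HMW-HA replicates 1 and 2. It spanned less, 0.219 and 0.187, in uLMW-HA replicate 2 and HMW-HA replicate 3. The count fell to 397 without HMW-HA replicate 2, as predicted if 1 library were the source. It also fell to 744 without replicate 1 and to 676 and 874 without uLMW-HA replicates 1 and 3. The falls therefore do not single out 1 library, and each fit had fewer samples. Without uLMW-HA replicate 2 the count was 2094. HMW-HA replicate 3 lay at -2.62 on the second principal component, where replicates 1 and 2 lay at 36.1 and 19.2. Without it the count rose to 4202, which argues against replicate 3 as the source. With only the compared groups in the fit the count was 354, so it also depends on the other groups. The spread within HMW-HA was the largest of the 6 groups (chi-square per gene 8.08 to 20.3, at most 7.66 elsewhere). A fit that shares its estimate of spread across groups may understate it, so the 2333 calls may be too many. Another library that stands apart and an effect of chain length both stay open.

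Other splits of the 6 libraries were too few for a share under 0.05 in the comparisons of 3 against 3. The real count and the highest of the other splits were 10671 and 1 for UVB (1 of 10 splits as large, the real one included), 11 and 1 for uLMW-HA (1 of 10), 26 and 0 for HMW-HA after UVB (1 of 10), 2333 and 0 for uLMW-HA against HMW-HA (1 of 10), 34 and 0 for the same after UVB (1 of 10), 10751 and 0 for UVB with uLMW-HA (1 of 10) and 10662 and 0 for UVB with HMW-HA (1 of 10). For HMW-HA against untreated they were 266 and 730 (2 of 10), and the larger split, HMW-HA replicates 1 and 2 with untreated replicate 1 against the rest, points to a structure of the samples. For uLMW-HA after UVB both were 0 by edgeR (10 of 10, as any split must give at least 0, so these splits tell nothing; 911 genes had an unadjusted p under 0.05 and DESeq2 called 3). For the interaction with uLMW-HA, where edgeR called 0 genes (1017 had an unadjusted p under 0.05 and DESeq2 called 4), 100 of 100 drawn splits gave as many and the highest other gave 1. Any split must give at least 0, so these splits test nothing.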

How the results depend on the processing

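The GC and length offsets were chosen only after the data were seen. Counts of genes changed for UVB alone and for UVB within each HA stayed within 1.5 times under each alternative. Other counts moved further, and the cause was not tested except where fewer or more genes or samples entered the fit. With no filter on low counts, edgeR called 164 genes for uLMW-HA (102 higher and 62 lower, against 1 and 10 with the filter), 539 for HMW-HA (302 and 237, against 96 and 170), 24 for uLMW-HA after UVB (17 and 7, against 0) and 70 for HMW-HA after UVB (11 and 59, against 1 and 25). It called 108 for uLMW-HA against HMW-HA after UVB (72 and 36, against 33 and 1), 28 for the interaction with uLMW-HA (18 and 10, against 0) and 107 for that with HMW-HA (55 and 52, against 25 and 2). With a filter of mean CPM 5, HMW-HA had 406, HMW-HA after UVB 42 and the HAs after UVB 70. With only the compared groups, HMW-HA had 74 (4 higher and 70 lower), uLMW-HA after UVB 5, the HAs without UVB 354 (195 and 159, against 960 and 1373) and after UVB 99 (82 and 17), and the interaction with HMW-HA 15. With DESeq2, uLMW-HA had 39 (12 higher and 27 lower, against 1 and 10), HMW-HA 403, uLMW-HA after UVB 3, HMW-HA after UVB 52, the HAs after UVB 93 (80 higher and 13 lower, against 33 and 1) and the interactions 4 and 42. With uniquely mapped reads, uLMW-HA had 17, HMW-HA after UVB 40 and the HAs after UVB 55, with exon reads the HAs after UVB had 55 and the interaction with uLMW-HA 3, and with GC and length offsets HMW-HA after UVB had 59 and the HAs after UVB 54, while uLMW-HA had 3 higher and 9 lower. The largest shift in the median of all genes was 0.0312, with GC and length offsets, and with RLE scaling it was 0.0138.

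Leaving out 1 library at a time gave 9815 to 10070 genes for UVB, 4 to 14 for uLMW-HA, 123 to 1648 for HMW-HA (lowest without HMW-HA replicate 2, with 18 higher and 105 lower, highest without replicate 3, with 1007 and 641), 0 to 1 for uLMW-HA after UVB, 18 to 31 for HMW-HA after UVB, 397 to 4202 for uLMW-HA against HMW-HA, 15 to 31 after UVB, 9911 to 10096 for UVB with uLMW-HA, 9660 to 10124 with HMW-HA, 0 to 0 for the interaction with uLMW-HA and 20 to 75 for that with HMW-HA. Each fit had fewer samples, and the cause of the higher counts (1648, 4202 and 75, each without HMW-HA replicate 3) was not tested. The overlap of UVB changes with opposite changes after UVB was 21 genes with DESeq2 for HMW-HA (8 with edgeR) and 1 for uLMW-HA (0). The overlap of independent lists was not computed for DESeq2. Genes lower with both HAs numbered 10 without UVB, 5 for uLMW-HA without UVB with HMW-HA after it, and 0 for the reverse, pairings that share no library but also change the UVB state and the number of calls. Of 231 list tests, 11 passed with an estimated correlation against 85 with the preset one. The correlation of the UVB change with gene span was 0.0622 among genes of mean CPM 5 or more, against 0.139. The change of MIRLET7DHG with UVB reversed to -0.51 in uniquely mapped reads and that of CSF1R to 1.34 in exon reads, and the cause was not tested. Among the named genes, calls were lost 2 times with RLE scaling, 5 with DESeq2, 10 with no filter, 0 with mean CPM 5, 2 with uniquely mapped reads, 5 with exon reads, 27 with only the compared groups, 10 with GC and length offsets and 140 with 1 library left out, and gained 5 times with DESeq2, 8 with no filter, 4 with GC and length offsets and 1 each with mean CPM 5, exon reads, only the compared groups and 1 library left out. Signs that flipped only where a gene was called in neither fit were not counted as reversed. With the replicate number as a block, uLMW-HA had 6 genes, 87 lists passed and 8 calls of named genes were lost. The numbers do not pair the samples: 0 of 27 same-number correlations exceeded 0.1 and 3 of 18 libraries matched their own number best. Depth limits genes with few reads, such as TSLP with 0 to 3 reads per library.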

Other observations

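The test of airway transcripts was chosen only after the result was seen. After UVB the changes with uLMW-HA were negatively correlated with the UVB response across genes, though no gene passed alone. Over 11853 genes with a mean of at least 5 CPM, the UVB effect measured in the HMW-HA arm and the effect of uLMW-HA after UVB, which share no library, had a covariance of -0.0100 (1.86e-05 in simulated unchanged groups) and a correlation of -0.272 (-0.296 to -0.180 with 1 library left out). The slope was -0.0433, so the opposition was small beside the UVB effect. The simulations drew each gene independently, so their covariance near 0 does not address trends that many genes share within a library. In the libraries of these comparisons, trends with transcript length spanned up to 0.488 on the log2 scale (HMW-HA replicate 2). The correlations here were not recomputed with GC and length offsets, so such a trend is not excluded as a source. For HMW-HA after UVB, with the UVB effect from the uLMW-HA arm, the covariance was 0.00480 (3.19e-05 simulated). The correlation was 0.114 (0.0458 to 0.156 with 1 library left out). The labels do not make clear that the UVB doses with and without HA were equal, and a difference in dose was not tested. The effects of HMW-HA without and after UVB had a covariance of 0.00427 (6.15e-05 simulated) and a correlation of 0.395. The effects of uLMW-HA and HMW-HA had a covariance below the simulated value of shared controls, 0.000603 against 0.00343 without UVB and 0.00218 against 0.00327 after it. Without UVB the sign was not stable: the correlation was 0.0452 (-0.117 to 0.198 with 1 library left out) and the Spearman correlation -0.109. After UVB the correlation was 0.341 (0.237 to 0.470 with 1 library left out).

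SCGB1A1, a secreted protein of airway club cells, stood at 1157 CPM in untreated HaCaT libraries. Airway secretory cells in the cultures are argued against, since the highest of 5 other airway secretory transcripts was 0.464 CPM (BPIFB1), with MUC5B at 0.352, MUC5AC at 0.0383 and no reads of SCGB3A1 or BPIFA1. Reads shared with a gene of near-identical sequence elsewhere are argued against, since at least 98.3% of its reads mapped uniquely in each untreated library. Unique mapping does not address reads of an overlapping or antisense gene, which could not be separated. FOXJ1, a regulator of motile cilia found in airway ciliated cells, goes the other way: it stood at 30.4 CPM in the same libraries and fell with SCGB1A1 after UVB, and other transcripts of ciliated cells were not tested.

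A hypothesis fixed before the data were examined was that photolesions stop elongation, so that long genes fall most. The Spearman correlation of the UVB change with gene span was 0.139 (0.0497 with uLMW-HA and 0.0831 with HMW-HA), which is above 0 rather than below it. The lowest median change was in the shortest of 5 classes of span in all 3 comparisons of all tested genes. Among genes of mean CPM 5 or more the correlations were 0.0622, -0.0346 and 0.116, and there the lowest class with uLMW-HA was the longest, where the hypothesis places it. The prediction was not borne out in all gene reads at the time of harvest, which the labels do not give. These reads came from poly(A) RNA and at most 5.61% were intronic, so they do not measure elongation itself. The correlations were not computed in intronic reads or with GC and length offsets. Whether photolesions stopped elongation is therefore not decided.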
